A study of Mus musculus with 12 samples.

How the data were processed

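Hearts of male C57BL/6 mice aged 10 to 12 weeks were profiled after intraperitoneal lipopolysaccharide (LPS, a bacterial cell wall component) at 5 mg/kg or after saline. Per the labels, hearts were taken 7 to 9 hr after the injection, total RNA was isolated with a mirVana kit, and each group held 6 mice. Each RNA was labelled with Cy3 and hybridised to a one-colour Agilent mouse miRNA array, so the series holds 12 arrays and 1 comparison, LPS against saline.

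Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.1.1 and hold linear intensity values per spot, background-subtracted in the processed signal column. Each array carried 49324 spots, of which 47160 were not controls, for 2982 probes of 1179 miRNAs. Of these miRNAs 1122 were from mouse and 57 from mouse herpesviruses. The deposited value table holds log2 values of the authors. Set against the scanner values, it equalled the log2 of the total signal summed over detected probes minus 1 constant per array, and undetected miRNAs were listed at the log2 of 0.1 minus the same constant. The origin of those constants is not given in the sources used here, and the column medians ran from -9.71 to -8.47. The table came in 2 copies with no difference, and all 1179 miRNAs matched it by accession, 1108 of them under the same name.

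Spots marked as non-uniform or as population outliers (3.73% to 4.66% of non-control spots per array) were left out, and no spot was saturated. The processed intensities of the spots of a probe were averaged on the linear scale. A probe counted as detected on an array where over 50% of its spots were well above background. Because 355 probes (11.9%) were detected on all 12 arrays, each array was divided by its 75th percentile over those probes. A floor was then set at the median over arrays of the 1st percentile of detected probes, -5.01 on the log2 scale, and log2 was taken. A miRNA was represented by its probe with the highest mean log2 value. Mouse miRNAs with a probe detected on at least 4 of 6 arrays of a group were tested, which gave 227 miRNAs, 198 of them detected on all 12 arrays. Values of 29 tested miRNAs lay at the floor on at least 1 array, and a fold change against the floor understates the change. Signal over background and the number of arrays limit the precision.

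LPS and saline were compared with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, with two-sided tests and Benjamini-Hochberg adjustment over the 227 miRNAs at an adjusted p under 0.05. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested, and again with an estimated correlation. The lists, by known biology, were miRNAs induced by NF-kB signalling, muscle miRNAs, leukocyte, erythroid, endothelial, smooth muscle, fibroblast and epithelial miRNAs, miRNAs of other organs, embryonic stem cell miRNAs, the let-7, miR-29, miR-30, miR-15/16, miR-181 and miR-34 families, the cluster of miR-17 and miR-92a, the miR-23/27/24 clusters, miR-210 of hypoxia, the Dlk1-Dio3 and Sfmbt2 clusters, miRNAs of cardiac hypertrophy, GC-rich small RNAs and viral miRNAs. For hairpins with both arms tested, paired by name, the difference of 5p minus 3p within an array was fitted in the same way. Single values were compared with two-sided exact permutation tests.

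The miRNAs named were up to 14 of each direction past the threshold, up to 4 members of each list with the smallest p, hairpins whose arms differed, and both arms of miR-21a, miR-146a, miR-155 and miR-223. The lists, this rule, the tests and most alternatives were fixed before the data were examined. The alternatives covered the scaling, background correction, signal per miRNA, floor, filter, deposited table, slide, replicate number, array weights, variance trend and leaving out each array. The total signal rebuilt from detected probes, the arrays of slide 1 alone, the Feature Extraction detection call and a fit of the 895 mouse miRNAs below the filter were added after the data were seen. That last fit used the scaled signal on the linear scale, without a floor, in thousandths of the array's 75th percentile.

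The fit was tested on simulated data for LPS against saline, with 40 of 227 miRNAs changed in each of 20 runs. In the same runs the 6 tested members of the NF-kB list were also shifted, by 0.6. Of the 40, the fit found 68.4% of changes of 0.3 on the log2 scale, 92.6% of changes of 0.6 and 98.2% of changes of 1.1. Of its calls 4.35% were false, where calls of the shifted list counted as calls and never as false. The simulated values had no floor and no slide difference, and more miRNAs changed than the 9 called in the data, so these shares may flatter the fit. The list shifted by 0.6 was called in 20 of 20 runs and an unshifted list in 0. However, the simulated miRNAs were independent of each other, and 83 of 100 splits of the real arrays gave at least 1 list shift. Probe positions are on mm9, per the file headers. The RefSeq gene table, on another mouse assembly (GRCm38), served only for the names of host and neighbouring genes, and positions in exons or introns were not analysed here.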

Results

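Cardiac miRNA was measured on 12 arrays, 6 from mice given LPS, which sets off a sepsis-like inflammation, and 6 from mice given saline. The comparison asks which miRNAs of the heart differ in the hours after LPS, a setting in which the labels describe weaker contraction on echocardiography. Between 210 and 257 mouse miRNAs were detected per array. The 75th percentile used for scaling was 438 intensity units on saline array 1 and 512 to 724 on the others. Correlations between arrays ran from 0.978 to 0.997, and no pair of arrays was identical. Slide 1 held all 6 saline arrays and LPS arrays 1 and 2, and slide 2 held the other 4 LPS arrays, so slide 2 alone gives no comparison. Scan sets followed the slides.

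Among the 227 tested miRNAs, with a floor under dim signals, miR-155-5p, an inducible regulator of innate immune signalling, rose the most after LPS, by 1.14 on the log2 scale (SE 0.06, 2.21-fold, adjusted p = 2.87e-08 by limma). Its log2 signal was -1.28 ± 0.10 (SD, n = 6) after LPS and -2.42 ± 0.10 (SD, n = 6) after saline. miR-29b-1-5p, the minor arm of a precursor of the miR-29 family, rose by 0.97 (SE 0.12, adjusted p = 0.000434), from -4.55 ± 0.15 to -3.59 ± 0.29 (SD, n = 6 each). miR-21a-5p, which is abundant in stressed and fibrotic hearts, rose by 0.68 (SE 0.09, adjusted p = 0.000453), from 1.92 ± 0.22 to 2.61 ± 0.11 (SD, n = 6 each). miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, rose by 0.65 (SE 0.09, adjusted p = 0.000766), from -2.37 ± 0.21 to -1.72 ± 0.12 (SD, n = 6 each). For each of these 4 miRNAs, the 6 LPS arrays lay above all 6 saline arrays.

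Rises were also found for miR-3096b-3p (log2 0.40, SE 0.08, adjusted p = 0.00733), miR-20b-5p (0.31, SE 0.05, adjusted p = 0.0034), miR-7a-5p (0.28, SE 0.06, adjusted p = 0.0183) and miR-17-3p (0.19, SE 0.04, adjusted p = 0.0238). All 6 LPS arrays lay above all 6 saline arrays for each of these 4 as well. miR-199b-5p, a miRNA of mesenchymal cells, fell by 0.31 (SE 0.07, adjusted p = 0.0141), with 5 of 6 LPS arrays below all saline arrays. In all, 9 of 227 miRNAs changed, 8 higher and 1 lower, 1 of them at least 2-fold, and 28 had an unadjusted p under 0.05. Of the 227, 198 (87.2%) had an absolute log2 difference under 0.25. The groups did not overlap for 8 miRNAs, all among the 9 changed, where chance gives 0.216% of miRNAs. miR-7a-5p was detected on 6 LPS arrays and 1 saline array, with all saline values at the floor, so its fold is understated and its rank is open, as the log2 fold change of mmu-miR-7a-5p was 0.07 with normexp, not past the threshold, and 0.68 with the rebuilt total signal. miR-17-3p was detected on 4 arrays of each group, with 3 saline values at the floor, and its log2 difference ran from 0.03 to 0.31 over 27 alternatives. miR-20b-5p has a near-identical relative on the array in miR-20a-5p, as miR-199b-5p has in miR-199a-5p, and signals within such families are uncertain.

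With slide as a block, miR-155-5p differed by 1.07 (SE 0.08), miR-29b-1-5p by 0.79 (SE 0.17), miR-21a-5p by 0.64 (SE 0.13) and miR-146a-5p by 0.64 (SE 0.14). These 4 stayed past the threshold by limma, the last 3 each at an adjusted p of 0.0385. Slide 2 held LPS arrays only, so every blocked difference is by construction that of slide 1 alone, 2 LPS arrays against 6 saline arrays. In the fit of slide 1 alone miR-155-5p (adjusted p = 0.000344) and miR-29b-1-5p (0.0267) passed, while miR-21a-5p and miR-146a-5p did not (0.182 each). The other 5 lost their calls with slide as a block. Their blocked log2 differences were 0.30 for miR-20b-5p (adjusted p = 0.13), 0.35 for miR-3096b-3p (0.267), -0.35 for miR-199b-5p (0.158), 0.17 for miR-7a-5p (0.703) and 0.15 for miR-17-3p (0.688). On slide 1 alone, where those 5 differences are the same by construction, none passed. The split of 8 higher and 1 lower became 4 and 2 with the percentile over all probes, 5 and 2 with quantile scaling, and 3 and 0 with no scaling. The count of lower miRNAs was 2 without LPS array 2 or saline array 4 and 5 without saline array 6, and the count at least 2-fold was 2 without LPS array 1, LPS array 6 or saline array 4.

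**Figure D1:**
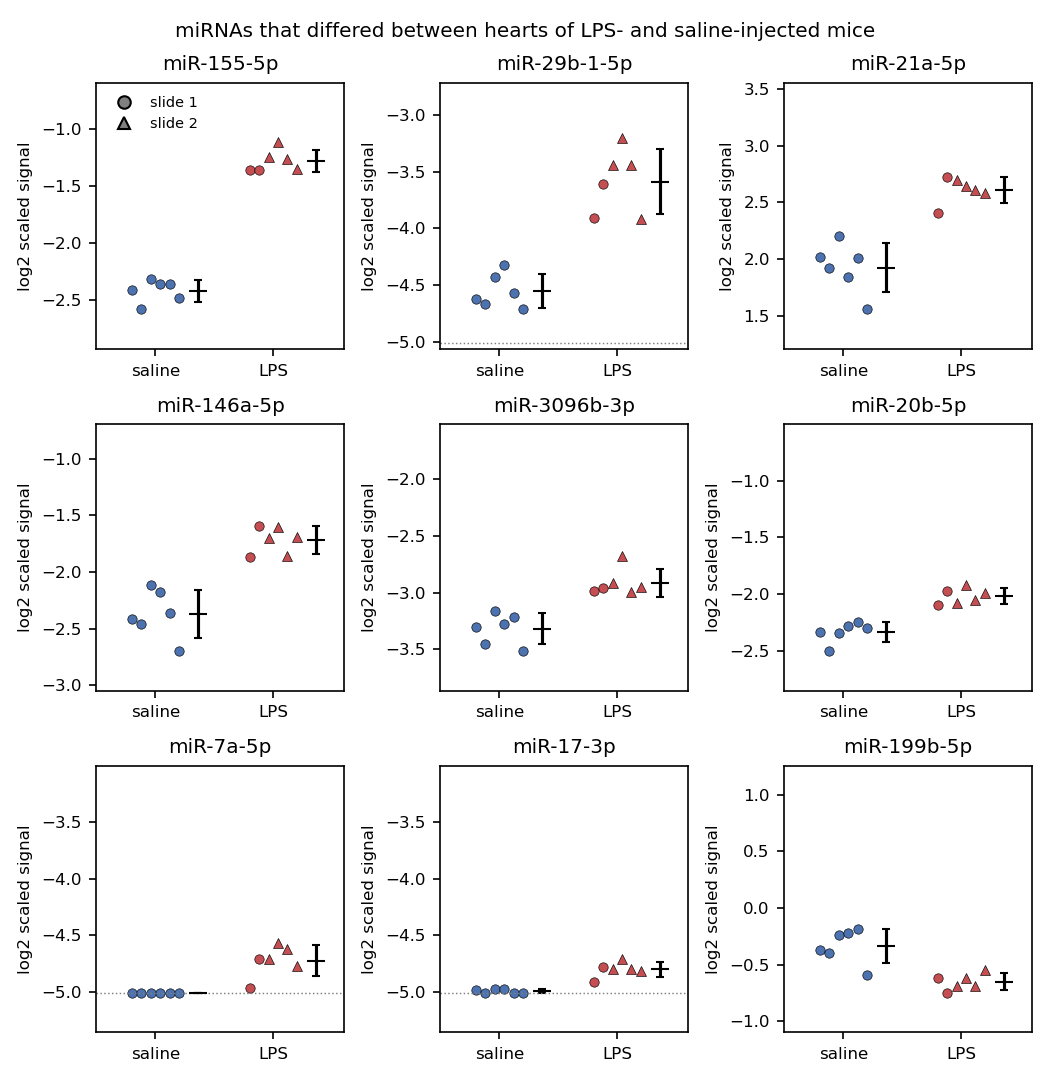
Log2 scaled signal of the 9 changed miRNAs on each array (saline blue, LPS red, circles for slide 1, triangles for slide 2, dotted line at the floor), with bars for the mean and SD of 6 arrays. For miR-155-5p the means were -1.28 after LPS and -2.42 after saline.

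The probe of miR-155-5p, ACCCCTATCACAATTAGC, matched chromosome 16 from 84714393 to 84714410 on mm9, and its gene lies inside the long noncoding RNA gene Mir155hg. The probe of miR-21a-5p, TCAACATCAGTCTGATAAGC, matched chromosome 11 from 86397588 to 86397607, and Mir21a lies inside Vmp1, a protein-coding gene of autophagy. The probe of miR-146a-5p matched chromosome 11 from 43187907 to 43187925, and Mir146 lies inside no other gene of the RefSeq table, between Atp10b and Gm5782. The probe of miR-29b-1-5p matched chromosome 6 from 31013028 to 31013049, next to Mir29a. Mir20b lies in a cluster on chromosome X with Mir106a and Mir363, Mir17 in one on chromosome 14 with Mir20a, and Mir199b inside Dnm1 on chromosome 2. A second probe gave a log2 difference of 1.16 for miR-155-5p, 1.09 for miR-21a-5p, 0.63 for miR-146a-5p, 0.36 for miR-20b-5p, 0.29 for miR-3096b-3p and -0.41 for miR-199b-5p. Its saline mean was -4.95 for miR-155-5p, -4.85 for miR-146a-5p and -5.01 for miR-3096b-3p. These lie near or at the floor of -5.01, so those differences may be understated. For miR-29b-1-5p 1 of 4 probes lay above the floor, and for miR-7a-5p and miR-17-3p 1 of 2 did.

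miR-21a-3p, the minor arm of the miR-21a precursor, had a scaled signal of 27.2 ± 4.72 thousandths (SD, n = 6) after LPS and -0.751 ± 1.48 (SD, n = 6) after saline. The difference of 28.0 thousandths (SE 1.85) had an adjusted p of 4.25e-08 by limma over the 895 miRNAs below the filter, with all 6 LPS arrays above all 6 saline arrays. It was the 1 miRNA of the 895 to pass. An unadjusted p under 0.05 was found for 51, near the 5% of miRNAs that chance gives. With slide as a block the difference was 23.2 (SE 2.05, adjusted p = 7.91e-06), which is by construction also the value of slide 1 alone. Both of its longest probes gave an exact permutation p of 0.00217, the smallest that 6 against 6 arrays can give. It was well above background on 1 LPS array and 0 saline arrays, and both means lay under the floor of 31.1 thousandths, so no fold is given. By that measure 0 miRNAs were detected on all 6 arrays of one group and none of the other, and by the Feature Extraction call 1 was, miR-21a-3p. The other arms fixed in advance, miR-146a-3p, miR-155-3p and miR-223-5p, were detected on 0 arrays.

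**Figure D2:**
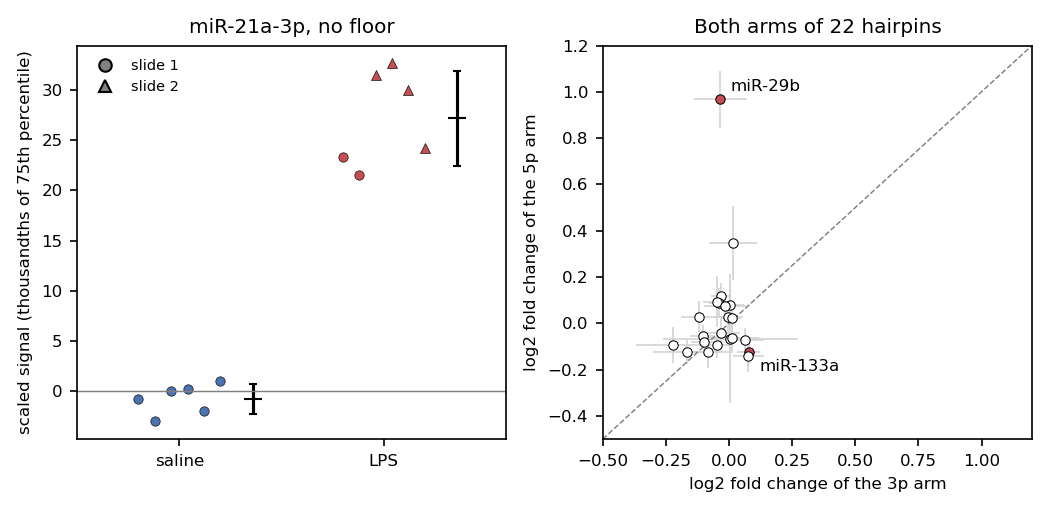
Left, scaled signal of miR-21a-3p on each array in thousandths of the 75th percentile (circles for slide 1, triangles for slide 2), with mean and SD, which were 27.2 ± 4.72 after LPS and -0.751 ± 1.48 after saline. Right, log2 fold change of the 5p arm against that of the 3p arm for 22 hairpins with their SE, where the dashed line marks equal change and red points are miR-29b and miR-133a, whose arms, paired by name, changed unequally.

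Among miRNAs known to be induced by Toll-like receptor and NF-kB signalling, 3 of 6 tested rose (miR-155-5p, miR-21a-5p and miR-146a-5p), and 4 did when adjusted over the list alone. The added member was miR-132-3p (log2 0.26, SE 0.09, adjusted p = 0.0185 over the list alone, 0.199 over all). miR-212-3p (0.22, SE 0.11) and miR-221-3p (0.20, SE 0.12) did not pass. All 6 pooled differences were above 0, with a median of 0.46, and camera gave an adjusted p of 6.53e-08. With an estimated correlation the adjusted p was 0.0654, past the threshold no longer. With slide as a block miR-212-3p differed by -0.01 (SE 0.14) and miR-221-3p by 0.12 (SE 0.18), so that 5 of 6 were above 0. The list shift of nfkb had a camera adjusted p of 4.2e-10 with slide as a block and 2.73e-09 on slide 1 alone. Both used the preset correlation of 0.01, while the pooled estimate for this list was 0.38, and both rest on the same 2 LPS arrays. They do not show that the shift is free of the slide. It was the 1 list of 16 to pass, and 0 passed with an estimated correlation. Without LPS array 1, LPS array 6 or saline array 6, 2 lists passed, the second being that of fibroblasts.

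Muscle miRNAs, which are abundant in cardiomyocytes, gave 0 of 7 past the threshold (camera adjusted p = 0.536). miR-133a-3p differed by 0.08 (SE 0.04), miR-133a-5p by -0.13 (SE 0.05), miR-133b-3p by 0.07 (SE 0.05) and miR-1a-3p by 0.06 (SE 0.05). Leukocyte miRNAs gave 0 of 4 (adjusted p = 0.676), with miR-223-3p of neutrophils at 0.19 (SE 0.10), miR-142-3p of blood cells at 0.01 (SE 0.11), miR-150-5p at 0.10 (SE 0.08) and miR-342-3p at -0.08 (SE 0.07). Erythroid miRNAs gave 0 of 3 (adjusted p = 0.185), with miR-451a at -0.35 (SE 0.16), miR-144-5p at -0.37 (SE 0.18) and miR-486-3p at -0.09 (SE 0.07). Fibroblast miRNAs had 1 of 4 lower, miR-199b-5p, also when adjusted over the list alone (camera adjusted p = 0.0906). miR-199a-5p differed by -0.10 (SE 0.06), miR-199a-3p by -0.05 (SE 0.06) and miR-214-3p by -0.09 (SE 0.06). Endothelial miR-126-3p (-0.0026, SE 0.06) and miR-126-5p (0.03, SE 0.06) did not pass, nor did miR-143-3p (0.14, SE 0.06) and miR-145a-5p (0.14, SE 0.07) of smooth muscle. With slide as a block the last 2 differed by 0.03 (SE 0.07) and 0.02 (SE 0.09), and the sign turned for 13 of 71 named miRNAs, none of them past the threshold, among them miR-1a-3p (-0.02), miR-133b-3p (-0.02), miR-142-3p (-0.02), miR-342-3p (0.03) and miR-126-5p (-0.05).

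**Figure D3:**
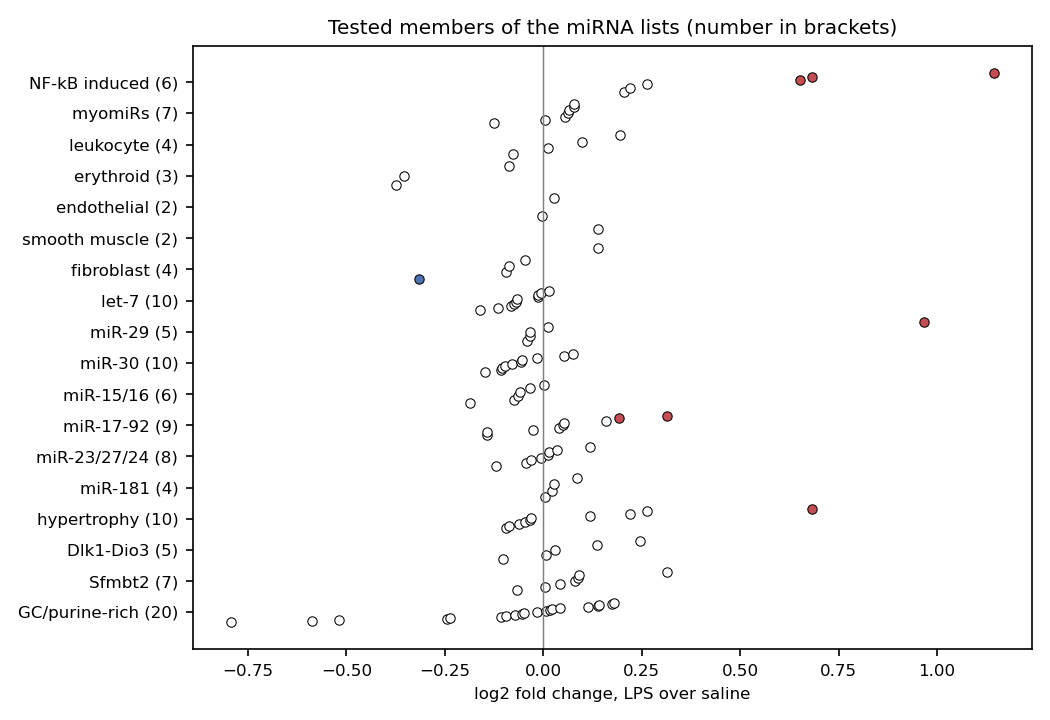
Log2 fold change of LPS over saline for each tested member of the lists with at least a pair of tested members, other organs aside, with the number tested in brackets. Each point is a miRNA, red where it rose, blue where it fell and open where it did not pass, and all 6 of the NF-kB list lie above 0, where miR-212-3p turns to -0.01 with slide as a block.

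The cluster of miR-17 and miR-92a and its paralogs, known for growth control, had 2 of 9 higher, miR-20b-5p and miR-17-3p (camera adjusted p = 0.274), also when adjusted over the list alone. miR-20a-5p differed by 0.16 (SE 0.07) and miR-25-3p by -0.14 (SE 0.07). The miR-29 family had 1 of 5 higher, the minor arm miR-29b-1-5p (camera adjusted p = 0.536), with a median of -0.03 and a mean of 0.17. Its other members, miR-29a-3p (0.01), miR-29b-3p (-0.03), miR-29c-3p (-0.03) and miR-29c-5p (-0.04), did not pass. Hypertrophy miRNAs had 1 of 10 higher, miR-21a-5p (adjusted p = 0.536), with a median of -0.03 and a mean of 0.09, and 3 of the 6 NF-kB members belong to that list as well. No member passed in the let-7 family (0 of 10, adjusted p = 0.185, let-7b-5p -0.16), the miR-30 family (0 of 10, 0.185, miR-30c-1-3p -0.15), the miR-15/16 family (0 of 6, 0.214, miR-15b-5p -0.19) or the miR-181 family (0 of 4, 0.676, miR-181a-5p 0.09). The same held for the miR-23/27/24 clusters (0 of 8, 0.751, miR-27a-3p -0.12), whose median was just above 0 and whose mean and test lay below it. It held for the Dlk1-Dio3 cluster (0 of 5, 0.751, miR-487b-3p 0.24 and -0.09 with slide as a block), the Sfmbt2 cluster (0 of 7, 0.751, miR-466h-3p 0.31) and GC-rich small RNAs (0 of 20, 0.536, miR-5126 -0.79). Lists too small for camera gave miR-192-5p at -0.05 and miR-194-5p at 0.10 (other organs), miR-290-5p at -0.15 (embryonic), miR-34a-5p at -0.06 and miR-210-3p at -0.08, none past the threshold. Epithelial miRNAs had 0 of 14 tested, and none of the 57 viral miRNAs entered the test.

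With arms paired by name, those of 2 of 22 hairpins changed unequally. For miR-29b, 5p minus 3p rose by 1.0 (SE 0.10, adjusted p = 2.23e-06 by limma), while miR-29b-3p differed by -0.03 (SE 0.11). miR-29b-3p also comes from the precursor of miR-29b-2, so this pair does not measure the arms of a single hairpin. With slide as a block the change was 1.06 (SE 0.14, adjusted p = 0.000157), by construction also the change on slide 1 alone (SE 0.08). For miR-133a, 5p minus 3p fell by 0.20 (SE 0.04, adjusted p = 0.00636), and with slide as a block the difference was -0.16 (SE 0.06, adjusted p = 0.269), so that call was lost. The arm difference of 29b was 0.25 with the mean of all probes of a miRNA (adjusted p = 0.18) and 0.08 with the listed total gene signal (0.617), and its call was lost in both. In the former, 3 of the 4 probes of miR-29b-1-5p lie at the floor and dilute its rise, and in the latter its listed total was off on 12 arrays, at a median of 618 times the rebuilt sum. Without LPS array 1 or saline array 6 the count of hairpins was 4.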

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

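The tests of slide, leukocytes and floor, those on viral probes and the strength of the response on slide 2, and the fit of miRNAs below the filter were chosen only after the results were seen, while those of the other 3 probes of miR-29b-1-5p and of miR-29a-5p were set beforehand, although the requirement that miR-29a-5p be detected was added after its signal was seen.

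Single arrays stood apart from the other 5 of their group in 13 of 193 groups, where chance gives about 9.65. miR-3096b-3p was -2.67 on LPS array 4, above the others, and miR-20b-5p was -2.50 on saline array 2, below the others. On saline array 2 miR-126-5p was low at -2.08, and on LPS array 2 miR-145a-5p was low at -2.85. LPS array 1 was low for miR-29b-3p (1.5) and miR-29c-3p (1.99), and saline array 6 for miR-30c-1-3p (-4.10). LPS array 4 was high for miR-322-5p (0.15), miR-27a-3p (2.09) and the mean of the miR-23/27/24 clusters (-0.25). Saline array 1 was high for miR-23a-5p (-4.93), and LPS array 6 was low for 5p minus 3p of miR-29b (-5.97). The effective feature size of saline array 1 was 0.6, the scanner software's default, against 0.824 to 0.849 elsewhere.

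Outside the tested miRNAs, the 4 viral probes detected on all arrays, of 57 on the array, had a mean log2 signal 0.15 higher after LPS than after saline (exact permutation p = 0.0433), in a test that ignored the slide, while within slide 1 the difference was -0.01. miR-21a-3p, below the filter, had a scaled signal of 27.2 thousandths after LPS against -0.751 after saline.

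miR-155-5p, miR-21a-5p, miR-146a-5p and miR-29b-1-5p were higher after LPS while most LPS arrays sat on their own slide. A difference between slides as the whole cause is argued against by their blocked values, the lowest of which was 0.64. This test was set after these 4 had kept their calls with the block, and it rests on the 2 LPS arrays of slide 1. On slide 1 alone miR-155-5p and miR-29b-1-5p passed, while miR-21a-5p and miR-146a-5p did not (limma adjusted p = 0.182 each). The differences of miR-20b-5p (0.31, SE 0.05, before and 0.30, SE 0.08, with the block), miR-3096b-3p (0.40, SE 0.08, and 0.35, SE 0.11) and miR-199b-5p (-0.31, SE 0.07, and -0.35, SE 0.10) changed little. Their highest unadjusted limma p was 0.0094 with the block, which argues against the slide as their whole cause, although their calls ended as the SE widened. That argument is weak, since these 3 were grouped by their blocked p after the results were seen. It also rests on the 2 LPS arrays of slide 1. For miR-7a-5p and miR-17-3p, near the floor, the highest such p was 0.0544 and slide and LPS cannot be told apart. Inflow of leukocytes would bring miR-142-3p and miR-223-3p, whose higher upper 95% bound was 0.404 pooled and 0.50 with slide as a block, so it stays open, since the content of miR-155-5p and the others in activated leukocytes was not measured. A response of heart cells to LPS may also account for the 4 rises and was not tested.

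miR-29b-1-5p rose while miR-29b-3p did not pass, but miR-29b-3p also comes from the precursor of miR-29b-2 and the listed match of its probe is on chromosome 1 from 196863287 to 196863307, so a signal from that precursor may hide a rise of the arm from miR-29b-1, which was not tested and stays open. Its other 3 probes, well above background on 0 arrays, had a summed signal of 23.97 ± 3.90 after LPS and 15.34 ± 2.76 after saline (exact permutation p = 0.00433), which argues against cross-hybridisation at a single probe but rests mostly on 1 of them (16.6 against 9.88, exact permutation p = 0.00433), as the others gave 5.29 against 3.78 (0.0736) and 2.12 against 1.67 (0.5). The probes overlap in sequence, so cross-hybridisation of another RNA with several of them was not tested and stays open. The floor is argued against by 0 values of either miRNA at it. The slide is argued against by a 5p minus 3p difference of 1.06 with slide as a block, which rests on 2 LPS arrays. Higher output of the transcript shared with miR-29a may be the cause, but miR-29a-5p was detected on 0 arrays, so its upper bound of 0.243, although under the rise, cannot show that it did not rise. The other arm of that hairpin, miR-29a-3p, showed no rise (0.01, SE 0.07, pooled and -0.07, SE 0.09, with slide as a block). The transcript itself was not measured.

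Among LPS arrays, miR-338-5p was 0.78 higher on slide 2 than on slide 1 (limma adjusted p = 0.00869), followed without passing by miR-1231-5p (0.65), miR-3058-5p (0.70) and miR-5122 (0.63). A difference between slides may be the cause. The mean of the 4 viral probes, which mouse hearts should not fill, was 0.24 higher on slide 2, without overlap. Within slide 1 it differed by -0.01 between LPS and saline. Both values rest on the 2 LPS arrays of slide 1. The probes also spread unequally over the LPS arrays, with an SD of 0.33 for mcmv-miR-m88-1-3p and 0.24 for mghv-miR-M1-2-3p. The SD was 0.07 for mcmv-miR-M23-1-3p and 0.05 for mcmv-miR-M23-1-5p. Which RNA fills these probes was not measured, so they may not be free of LPS. A stronger response in the mice of slide 2 stays open, since the median signed slide difference of the 9 changed miRNAs was 0.070 with an SD of 0.090, while the bound set for it was 0.101 (their median change of 0.405 divided by 4). Of the 9, 8 lay further in the direction of their change on slide 2, but they were called in a fit with most LPS arrays on that slide.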

How the results depend on the processing

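The alternatives that used slide 1 alone, the rebuilt total signal, the Feature Extraction call and the fit below the filter were chosen only after the data were seen, as was the naming of miR-3102-5p. No called difference turned its sign in 28 alternatives, of which 12 left out 1 array each, whereas 38 of 71 named miRNAs, none of them called in either fit, turned theirs under at least 1, 4 of them with the listed total gene signal alone, and 13 did with slide as a block. That listed total was off for miR-7a-5p on 12 arrays and for miR-17-3p on 10, so their lost calls with it tell nothing. miR-155-5p stayed past the threshold in 28 of 28 (log2 0.81 to 1.19), miR-21a-5p in 27, miR-29b-1-5p in 27, miR-146a-5p in 26, miR-199b-5p in 23, miR-20b-5p in 22, miR-3096b-3p in 21, miR-7a-5p in 18 of 27 and miR-17-3p in 10 of 27. The log2 fold change of mmu-miR-7a-5p lost its call without LPS array 3 (adjusted p = 0.0535) or LPS array 5 (0.0579). The log2 fold change of mmu-miR-17-3p lost it without LPS array 2, 3, 5 or 6 or saline array 1 or 2 (0.0513 to 0.0781). Of 62 named miRNAs that had not changed, 7 passed under at least 1 alternative.

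The count of 9 changed miRNAs was 3 with no scaling, 4 with slide as a block, 15 with array weights and 2 on slide 1 alone, which holds fewer arrays. Of the 8 higher, the count was 4 with the percentile over all probes, 5 with quantile scaling, normexp, the listed total gene signal or the deposited table, 3 with no scaling, 4 with slide as a block and 2 on slide 1 alone. The 1 lower, miR-199b-5p, became 2 with the percentile over all probes (miR-3102-5p and miR-5126 in its place) or quantile scaling (with miR-27a-3p), 3 with the deposited table, 6 with array weights, and 0 with no scaling, slide as a block or slide 1 alone. The 1 at least 2-fold became 0 with normexp and 2 with the rebuilt total. The 1 list became 3 with normexp, 4 with array weights and 0 with an estimated correlation. The 2 arm differences became 1 with quantile scaling, the listed total, the mean of all probes, slide as a block or slide 1 alone, 4 without a filter and 6 with array weights. Detection in one group alone was 0, and 1 by the Feature Extraction call. Leaving out 1 array gave 7 to 13 changed, 6 to 11 higher, 1 to 5 lower, 1 to 2 at least 2-fold, 1 to 2 lists and 2 to 4 arm differences. Without a filter the added hairpins were miR-21a and miR-7a. Both means of miR-21a-3p lay under the floor of 31.1 thousandths (27.2 after LPS, -0.751 after saline), so unequal arms are not shown for miR-21a. miR-29b was lost with the listed total, which was off for miR-29b-1-5p on 12 arrays. It was also lost with the mean of all probes, where 3 of 4 of miR-29b-1-5p lay at the floor. Apart from these cases and the smaller set of slide 1, the cause of the moves was not tested.

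The replicate numbers did not pair the arrays: residual correlations of the same number ran from -0.734 to 0.262, 3 of 6 were over 0.1, and 0 LPS arrays correlated best with their own number. With the replicate block 7 miRNAs were called, 6 higher and 1 lower, miR-3102-5p in place of miR-199b-5p, with 1 list and 3 arm differences. The signal difference of mmu-miR-21a-3p passed in every fit below the filter, from 23.2 to 29.1 thousandths. The count of such miRNAs was 2 with slide as a block, with the replicate block or without LPS array 6, 3 on slide 1 alone and 4 without a trend. Signals near background limit miR-7a-5p, miR-17-3p and miR-21a-3p.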

Other observations

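The counts over other splits of the arrays were tests chosen only after the results were seen, apart from that for miRNAs below the filter, and for higher and lower counts the larger direction of each other split was used, a choice made after a first run.

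Just short of the threshold, miR-101b-3p differed by 0.21 (limma adjusted p = 0.0656) and miR-3102-5p by -0.80 (0.0849). The GC-rich small RNAs miR-5126 (-0.79) and miR-2861 (-0.59) did not pass. Below the filter, the groups did not overlap for 5 miRNAs, where chance gives 1.94. Higher after LPS were the signals of miR-21a-3p, miR-146b-5p (20.68 against 14.04 thousandths, adjusted p = 0.161), miR-370-3p (24.1 against 16.5, 0.188) and miR-203-3p (17.9 against 13.2, 0.287), and lower was that of miR-411-3p (0.306 against 2.60, 0.294). miR-146b-5p shares its seed with miR-146a-5p, and their probes are similar in sequence. These were chosen after their values were seen.

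The total gene signal column of the scanner files differed by over 1% from the sum of detected probe signals for 69 to 84 miRNAs per array, 38 of them on every array and 54 of the tested ones on at least 1. For miR-29b-1-5p the listed total was off on 12 arrays, at a median of 618 times the rebuilt sum.

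Of the 462 splits of the 12 arrays into equal groups, 100 were drawn, the real one included. As many changed miRNAs as the real 9 came in 3 of 100, with 23 as the highest of the others, which is under 5% and argues against chance for that count. As many as the 8 higher came in 4 of 100 (highest other 23), and as many as 1 at least 2-fold in 2 (highest other 1), also under 5%. The counts were not adjusted for each other, and the splits ignore the slide. They therefore neither exclude chance nor set LPS apart from the slide. Among the other splits, 1 with 8 in the same direction set LPS array 2 and saline array 3 with the arrays of slide 2. It kept all LPS arrays but array 1 together, so its calls cannot be credited to the slide alone. With slide as a block 4 miRNAs were higher. The 2 arm differences came in 1 of 100, the real split (highest other 1). Shares of 5% or more came for the 1 lower miRNA (5 of 100, highest other 23), for 1 list shift (83 of 100, highest other 7) and for 1 miRNA below the filter (5 of 100, highest other 25), so chance stays open there. The split with 23 calls set LPS arrays 1, 2, 3 and 6 with saline arrays 2 and 6 against the rest, with 2 arrays of slide 2 on each side. A structure of the samples may lie behind that count, which was not tested. Of the drawn splits, 3 others kept slide 2 together and gave 0, 0 and 8 changed miRNAs, against the real 9. Their highest count in the larger direction was 8, equal to the real 8 higher. With slide as a block, the 28 splits within slide 1 gave 4 calls for the real split and at most 0 for the others.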
